A study of Homo sapiens with 6 samples.

How the data were processed

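RNA from K562 cells was labelled with biotin and hybridised to Affymetrix Human Genome U133 Plus 2.0 arrays, per the labels' protocols. 2 samples carried an empty vector and 4 a CTCF expression vector, and their groups and replicate numbers were taken from the sample titles. The deposited table holds 1 intensity per probe set and array on a linear scale, from the authors' own processing. The software, background correction, probe set summary and normalization behind it are not given in the sources used here. The array medians were close, so the values were used with no further normalization. The upper quartiles differed more, from 156 to 205, and quantile normalization was run as an alternative. The authors' deposited table of selected probe sets gives group means, a signed fold change with its bounds and a difference of means. These were used as scores of the authors, and its header states averages weighted by standard error and the selection on the lower bound and the difference. Its baseline means match the mean of the 2 empty vector arrays, with a median absolute log2 difference of 0.00318, where every other pair of arrays gives at least 0.524.

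Values were analysed as log2(value + 16) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated statistics, 2-sided). All 54613 probe sets that are not among the 62 AFFX controls were tested, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The fit fixed before the data were examined has an intercept and the group. A second fit, added after the data were examined, has the array set as a block. The sets come from hierarchical clustering of the arrays on 42 spike-in control probe sets, and each holds both groups: 1 empty vector and 1 CTCF array in the smaller set, 1 and 3 in the larger. Within-set values are differences of log2 values in 1 set, with no test in the smaller set. No scan date or slide was used here.

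Probe sets were named from GEO's platform annotation: 41091 have 1 gene, 1801 have several and 11721 are not listed, and only those with 1 gene were named. Of the 41091, 41037 were matched by Entrez ID to a RefSeq gene table (GRCh38.p14), which updated symbols and ordered genes along chromosomes. No genome build is named by the deposited files, so no coordinates are given. Where a gene has several probe sets, the one with the highest mean log2 value over the 6 arrays was used, giving 19775 genes. In tests of lists and runs of genes on fewer arrays, that choice was made again on the arrays kept. Probe sets for several globin genes, among them those shared by alpha-globin or gamma-globin copies, were therefore not named.

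Gene lists were fixed before the data were examined. The 33 lists with 5 or more measured genes were tested against all other genes with camera, using a preset correlation between genes of 0.01, 2-sided, adjusted over the lists. Camera with an estimated correlation, camera on ranks and fry, which tests a list without comparing it with other genes, were alternatives. Consecutive runs of 40 measured genes were tested in the same way. The genes named in the text follow a rule fixed before the data were examined, applied to each fit. It takes CTCF and CTCFL. It takes the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with non-overlapping groups, a higher group's mean above the median of all probe sets and a symbol other than a LOC, LINC or orf name. It takes up to 3 members past the threshold with the largest change per list, or the brightest member of a list with none. It takes the 3 largest rises and falls of the authors' deposited table, and 3 genes of each run of genes past the threshold.

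The method was tested on simulated data. Each fit was run on simulated arrays with the real probe set means and array sets, in which 200 of 54613 probe sets, all with a mean above the median, were changed. For the comparison of CTCF with empty vector, the blocked fit recovered 54% of the 2-fold and 97% of the 4-fold changes, with 10 false among 161 calls, and the fit without the block recovered 0% of either. Camera called 5 of 5 lists shifted by 0.5 on the log2 scale and 0 of the others, and 1 of 1 shifted run of genes and 0 of the others. With an estimated correlation it also called 5 of 5 shifted lists. The simulated noise was independent between genes, so these calls do not bear on lists of correlated genes. The simulated means held the array set term and the variances were drawn toward their median, which favours the blocked fit.

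Alternatives tried were quantile normalization, median centring, leaving out dim probe sets, a variance trend with robust variances, array weights, the replicate number as a block, pseudocounts of 1 and 64, a threshold of 0.01, the mean of all probe sets of a gene, runs of 20 and 80 genes, and leaving out each array in turn. Each was run without and, after the data were examined, with the array set as a block, apart from the replicate number, which with the array set leaves no residual degrees of freedom. The larger array set alone was also fitted, after the data were examined. Figures were drawn with matplotlib 3.10.9.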

Results

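Expression was measured in K562, an established human leukemia cell line with erythroid and megakaryocytic features, on 6 arrays of 54675 probe sets. 2 arrays came from cells stably carrying an empty expression vector and 4 from cells stably carrying the same vector with CTCF, the zinc finger protein that binds insulators and, with cohesin, anchors chromatin loops. The comparison asked which transcripts differ when CTCF is overexpressed, with the empty vector cells as baseline. The CTCF cells are a single named transfectant, so an effect of CTCF and a property of that transfectant cannot be separated by these arrays. A property of the empty vector cells that serve as baseline cannot be separated from them either. Median expression values were alike, from 28.8 to 34.2 per array, and 35.1% to 38.6% of the probe sets lay below 16. The number of arrays limits the precision, and because the labels do not say whether replicates came from separate cultures, p-values measure only the spread between these samples, which may be technical.

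The arrays fell into 2 sets that crossed the groups. Empty vector array 1 and CTCF array 4 formed the smaller set, and empty vector array 2 with CTCF arrays 1, 2 and 3 formed the larger set. The sets were read from bacterial and phage spike-in probe sets, which match no human transcript. The thr spike-in had values of 47.7 and 52.9 in the smaller set and 288 to 541 in the larger set. Pearson correlations across the human probe sets, which are not independent replicates, were 0.966 to 0.991 for the 7 pairs of arrays within a set. They were 0.877 to 0.907 for the 8 pairs between sets, and the first principal component, with 74.9% of the variance, separated the sets. The difference of the 3' and 5' control probe sets of ACTB was 0.81 and 0.91 on the log2 scale in the smaller set and 0.22 to 0.28 in the larger set, while that of GAPDH was -0.15 to -0.11 over all 6 arrays.

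**Figure D1:**
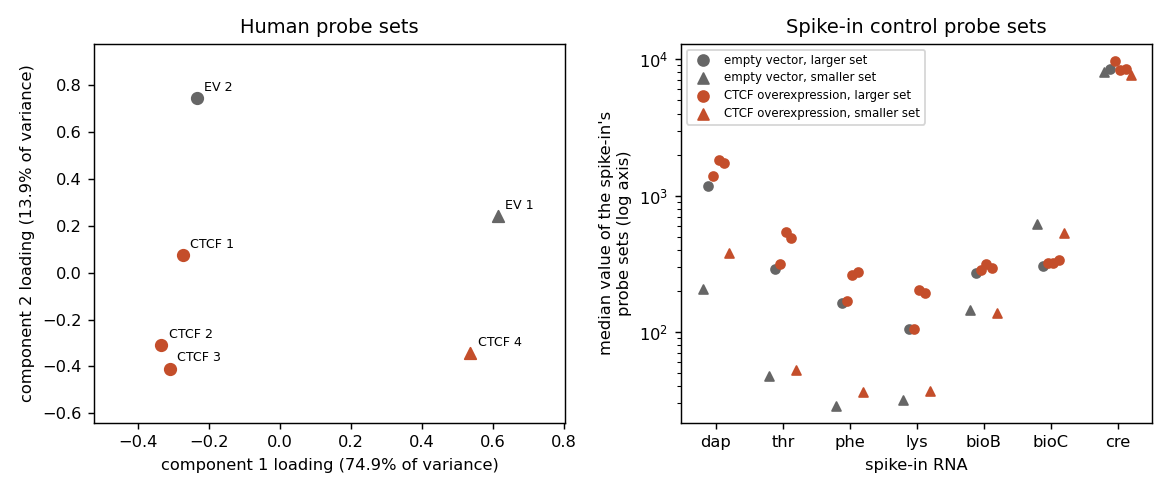
The left panel plots each array's loading on the first 2 principal components of the log2 human probe set values, and the right panel plots each array's median value over the probe sets of each spike-in RNA on a log axis. Grey marks empty vector (EV) arrays, orange marks CTCF arrays, and triangles mark the smaller array set, which lies apart from the larger set on component 1, with 74.9% of the variance.

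How many transcripts changed cannot be read from the calls, since simulated 2-fold changes were recovered at 54% with the array set block and 0% without. More of the called transcripts were lower than higher in the CTCF arrays. Among these the largest falls were those of the trypsinogen family (PRSS3, PRSS2, PRSS3P2), DLK1, TFPI2 and COL1A2, all by more than 4 on the log2 scale, and among the genes that the naming rule ranks, with 1 probe set each, the largest rises were those of PWAR6, HBD, FMR1NB and PTPRC. In the fit chosen before the data were examined, which compares the groups with no other term, 6 probe sets passed a Benjamini-Hochberg adjusted p of 0.05 in limma, 2 higher and 4 lower in the CTCF arrays, and 3729 had an unadjusted p under 0.05. With the array set as a block, a term added after the data were examined, 1017 of 54613 probe sets passed, 294 higher and 723 lower, and 679 of them changed by at least 2-fold, 189 up and 490 down. In that fit 9631 probe sets had an unadjusted p under 0.05 in limma. At the level of 1 probe set per gene, 508 of 19775 genes passed in the blocked fit, 123 higher and 385 lower, against 3 without the block. From here on, rose and fell refer to the blocked fit at an adjusted p under 0.05, and log2 changes are its coefficients ± SE, CTCF over empty vector. All 1017 probe sets changed in the same direction within each array set, and for 809 of them every array of one group lay above every array of the other. Both are largely fixed by the selection, since a small residual in the blocked fit already needs the sets to move alike. Over all probe sets, 13.2% separated the groups in that way. Chance gives 13.3% only for exchangeable arrays, which the array sets contradict, so the 2 shares do not test whether the groups differ. Higher probe sets made up 28.9% of the calls with the values as deposited and 42.4% of 1207 calls after quantile normalization. As deposited, the upper quartile was 205 in empty vector array 2 and 182 to 192 in the CTCF arrays of the larger set. In the smaller set it was 161 in the empty vector array and 156 in the CTCF array. The call counts depend on which arrays are fitted. With the block, leaving out empty vector array 1 or CTCF array 4 lets the block absorb the other array of the smaller set. Both fits then equal that of the larger set alone, where the single empty vector array adds nothing to the measured spread. The blocked fit made 0 calls without empty vector array 1, empty vector array 2, CTCF array 2 or CTCF array 4, 8 without CTCF array 3 and 762 without CTCF array 1. In the larger set alone limma made 0 calls, with 7699 probe sets at an unadjusted p under 0.05. All 1017 log2 changes kept their sign in each of these fits, which their selection on the same arrays also largely fixes.

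**Figure D2:**
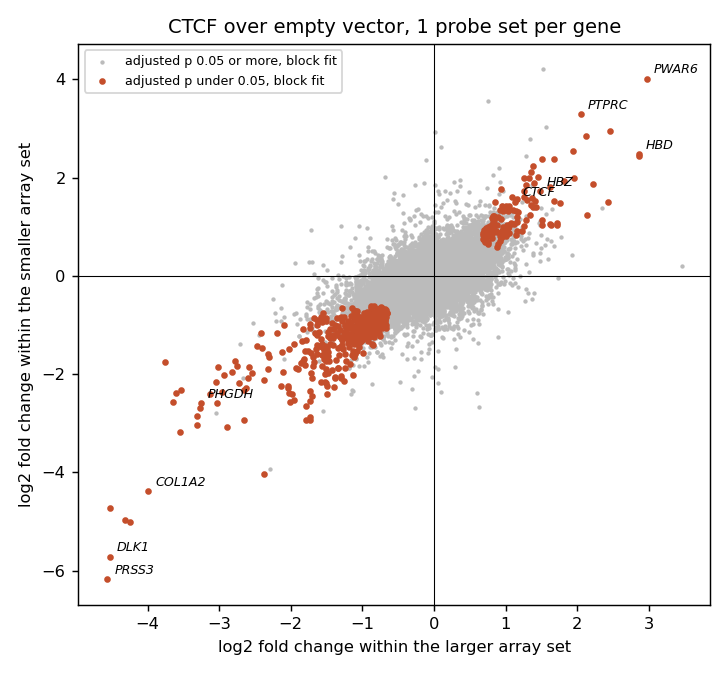
Each point is 1 gene, with the log2 fold change of CTCF over empty vector within the larger array set (1 against 3 arrays) on the horizontal axis and within the smaller set (1 against 1 array) on the vertical axis. Orange marks the 508 genes past an adjusted p of 0.05 in the blocked fit, all of which lie in the quadrants where both sets change in the same direction, as their selection in that fit largely requires.

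CTCF itself was higher in every CTCF array. Its probe set (202521_at) had values of 457 and 634 in the empty vector arrays and 1311, 1614, 1332 and 1332 in the CTCF arrays, a mean of 545 ± 125 (SD, n = 2) against 1397 ± 145 (SD, n = 4). The log2 change was 1.29 ± 0.16 in the blocked fit (adjusted p = 0.0288), a 2.44-fold rise, and 1.34 without the block (adjusted p = 0.199). Within the smaller and larger array sets it was 1.51 and 1.14. With the block, leaving out either array of the smaller set gives the same fit as the larger set alone. The call ended, with adjusted p of 0.106 to 0.398, when empty vector array 1, empty vector array 2, CTCF array 2, CTCF array 3 or CTCF array 4 was left out, and it had an adjusted p of 0.0476 without CTCF array 1. A probe set of this 3' array type may read a part of the transcript that a cDNA vector need not carry, so the probe set reports the endogenous transcript, the vector's or both. CTCFL, a paralog of CTCF on the list of cancer-testis antigens (probe set 1552368_at), had values of 3459 ± 211 in the empty vector arrays (SD, n = 2) and 2468 ± 237 in the CTCF arrays (SD, n = 4). Its log2 change of -0.47 ± 0.14 did not pass in the blocked fit (adjusted p = 0.16). Adjusted over the list alone, which holds only CTCF and CTCFL, 1 was higher and 1 lower.

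The 12 genes with the largest rises under the naming rule included HBD and HBBP1 of the beta-globin locus and the cancer-testis antigens FMR1NB and MAGEB1. PWAR6, a noncoding RNA of the imprinted Prader-Willi region, rose by 3.39 ± 0.43 from 6.45 ± 1.66 (SD, n = 2) to 221 ± 111 (SD, n = 4). HBD, which encodes delta-globin, rose by 2.71 ± 0.29, and its neighbour HBBP1, a globin pseudogene whose sequence resembles that of other globins, by 2.18 ± 0.17. PTPRC, which encodes the leukocyte phosphatase CD45, rose by 2.55 ± 0.32, from 182 ± 93.3 to 1137 ± 218. FMR1NB and MAGEB1 rose by 2.70 ± 0.18 and 1.86 ± 0.22. HDAC9, a class II histone deacetylase, rose by 2.42 ± 0.35, CXCL11, a chemokine, by 2.07 ± 0.24, and AKR1C3, an aldo-keto reductase, by 1.96 ± 0.18. RRP15, a ribosomal RNA processing factor, rose by 1.86 ± 0.19, TMEM201, an inner nuclear membrane protein, by 1.97 ± 0.18, and DCAF4L2 by 2.09 ± 0.16. Where a gene has several probe sets, 2 of 2 passed for PWAR6, CXCL11 and DCAF4L2, 3 of 5 for PTPRC, 1 of 5 for HDAC9, and 1 of 2 for RRP15 and TMEM201, whose other probe set had the opposite sign for TMEM201. Adjusted p-values of these 12 genes lay below 0.05 in the blocked fit and above it in the fit without the block. Fold changes were computed with 16 added to each value and so understate the change of transcripts with low values, such as FMR1NB at 9.95 ± 5.61 and CXCL11 at 10.1 ± 5.27 in the empty vector arrays.

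The 12 genes with the largest falls had means of 146 to 2706 in the empty vector arrays and of 1.54 to 116 in the CTCF arrays. DLK1, an imprinted gene for a transmembrane protein related to Notch ligands, fell by 5.00 on the log2 scale (SE 0.41), from 2084 ± 12.7 (SD, n = 2) to 66.1 ± 39.6 (SD, n = 4), and COL1A2, a chain of type I collagen, fell by 4.14 (SE 0.15), from 1690 ± 167 to 89.5 ± 20.7. TFPI2, a Kunitz-type protease inhibitor, fell by 4.60 (SE 0.25), 24.3-fold. The probe set named for the trypsinogen gene PRSS3 fell by 5.21, that for PRSS2 fell by 4.57 and that for PRSS3P2 fell by 4.55. Since these near-identical copies may cross-hybridise, which of them changed is uncertain. ASS1, which encodes the arginine-synthesis enzyme argininosuccinate synthase, fell by 3.40 (SE 0.21), P2RX1, an ATP-gated cation channel, by 3.13 (SE 0.19), and ETS1, a transcription factor, by 3.11 (SE 0.31). SYTL5 fell by 3.21, PELI2 fell by 3.19 and SRPX fell by 3.04. Of several probe sets, 3 of 3 passed for COL1A2, 2 of 2 for TFPI2, PRSS2 and PRSS3, 1 of 3 for ETS1, and 1 of 2 for SYTL5, PELI2 and DLK1, whose other probe set had 0.12 for DLK1. Of all these, PRSS2, PRSS3P2 and COL1A2 also passed without the block, with adjusted p of 0.0179, 0.0179 and 0.038. The other probe sets to pass without the block, chosen here after their values were seen, were a second PRSS2 probe set (216470_x_at) and a pair of higher ones that carry no single gene name. The annotation gives 2 genes for 206042_x_at, with means of 14.9 ± 1.90 and 627 ± 27.0, and does not list 204466_s_at, with means of 28.8 ± 10.5 and 377 ± 28.4 (SD, n = 2 and 4).

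**Figure D3:**
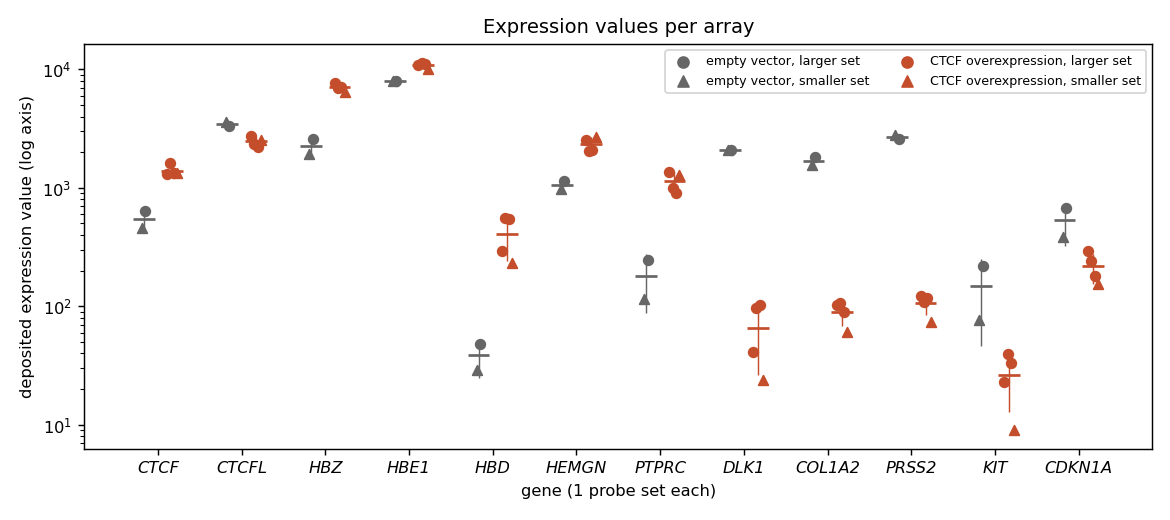
Expression values of 12 of the named genes are drawn per array on a log axis, grey for empty vector and orange for CTCF, with triangles for the smaller array set, horizontal lines at the group means and vertical lines of 1 SD. CTCF lies at 457 and 634 in the empty vector arrays and at 1311 to 1614 in the CTCF arrays, while DLK1, COL1A2 and PRSS2 lie far lower in every CTCF array.

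Some globin transcripts were higher in the CTCF cells. Of the 6 globin genes with a probe set of their own, 2 rose, 3 did so when p-values were adjusted over the list alone, and none fell. HBZ, the embryonic zeta-globin, rose by 1.58 ± 0.13, from 2260 ± 468 (SD, n = 2) to 7038 ± 508 (SD, n = 4), and HBD rose as given above, while HBE1, the embryonic epsilon-globin, had values of 8002 ± 59.6 and 10862 ± 593 and a log2 change of 0.41 ± 0.11 (adjusted p = 0.136). HBB, for beta-globin, was read differently by its probe sets. The one with the highest mean (1562981_at), which read 618 and 445 in the smaller array set and 136 to 153 in the larger, had a log2 change of -0.12, while the other 3 rose by 1.52 to 2.25 and may read related globins. As a list, the globins were shifted upward against all other genes (camera adjusted p = 0.00124; median log2 change 0.40, and 0.33 and 0.48 within the smaller and larger array sets), a call that had an adjusted p = 0.536 with an estimated correlation and 0.0702 without empty vector array 2. The wider list of 46 erythroid markers and regulators split: 2 rose, 0 fell, and 10 were higher and 7 lower when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0793, 0.046 without CTCF array 4 and 0.0177 in the larger array set alone, but 0.536 with an estimated correlation). The lower values without CTCF array 4 and in the larger set are not separate results, since the block absorbs empty vector array 1. They differ from each other because the probe set of each gene was chosen again on the arrays kept. HEMGN, a nuclear regulator of blood cells, rose by 1.14 ± 0.17 and ADD2, a membrane skeleton protein, by 1.00 ± 0.14. Among 27 genes of heme synthesis and iron, 0 passed (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.334), and FTL, for ferritin light chain, had a log2 change of 0.14 ± 0.11.

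The lists of MYC-induced nucleolar genes and of RNA polymerase I were shifted upward, mostly by changes too small to pass one by one, and that of ribosomal proteins was not called. Of 48 MYC-induced nucleolar genes, 1 rose over all genes tested, and 33 were higher and 0 lower adjusted over the list alone. The median log2 change was 0.59, with 0.44 and 0.62 within the smaller and larger array sets (camera adjusted p = 4.38e-15, but adjusted p = 0.536 with an estimated correlation). RRP12, which acts in the export of ribosomal subunits, rose by 1.01 ± 0.12, and NPM1, the abundant nucleolar chaperone, had a log2 change of 0.07 ± 0.11. In the list of RNA polymerase I and rDNA transcription, 1 of 24 genes rose and 1 fell, 11 and 1 when adjusted over the list alone, with a median of 0.41, and 0.44 and 0.39 within the sets (camera adjusted p = 7.02e-05, but 0.536 with an estimated correlation). Its polymerase subunits POLR1E and POLR1D moved apart, the first rising by 0.83 ± 0.12 and the second falling by 0.71 (SE 0.11), while FBL, for fibrillarin, had 0.28 ± 0.11. These lists share 2 genes. MYC itself had values of 3856 ± 641 (SD, n = 2) and 3249 ± 468 (SD, n = 4) and a log2 change of -0.31 ± 0.16 (adjusted p = 0.394), and 0 of the 12 genes of the MYC network passed, nor adjusted over the list alone (camera adjusted p = 0.141). Of 52 ribosomal protein genes, 0 passed, with a median of 0.02, RPS16 at 0.04 ± 0.11 and a camera adjusted p = 0.517.

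Heat shock, proteasome and histone genes were also shifted upward, and genes of the unfolded protein and ATF4 response downward. Among 20 heat shock genes, 1 rose (9 higher and 0 lower adjusted over the list alone), with a median of 0.42, and 0.26 and 0.53 within the smaller and larger sets (camera adjusted p = 7.02e-05, but adjusted p = 0.536 with an estimated correlation), HSPH1, a chaperone of the HSP110 family, rising by 1.30 ± 0.14 and HSPD1 at 0.32 ± 0.11. Among 29 proteasome and ubiquitin genes, 0 passed (4 and 0 adjusted over the list alone), with a median of 0.28, and 0.25 and 0.27 within the sets (camera adjusted p = 1.6e-06, but adjusted p = 0.536 with an estimated correlation), and UBB had a log2 change of 0.10 ± 0.11. Of 28 core and linker histone genes, 1 rose (9 and 1 adjusted over the list alone), H2BC11 by 1.11 ± 0.18, with a median of 0.34, and 0.22 and 0.32 within the sets (camera adjusted p = 0.000122, but adjusted p = 0.536 with an estimated correlation). The 37 genes of the unfolded protein and ATF4 response had a median of -0.27, and -0.22 and -0.44 within the sets (camera adjusted p = 0.001, but adjusted p = 0.536 with an estimated correlation and 0.0702 without empty vector array 2). Of these genes 0 rose and 2 fell, 0 and 6 adjusted over the list alone. PHGDH, the first enzyme of serine synthesis, fell by 2.99 (SE 0.47), from 3388 ± 500 to 444 ± 234. SEL1L, which acts in the degradation of misfolded endoplasmic reticulum proteins, fell by 1.22 (SE 0.12), while MTHFD2 had -0.38 ± 0.27.

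Cell cycle lists moved little. The 49 G1/S genes were shifted upward by a median of 0.12, with 0.08 and 0.11 within the sets (camera adjusted p = 0.0159), but 0 of them passed, nor adjusted over the list alone, and the call had an adjusted p = 0.536 with an estimated correlation and 0.0769 without empty vector array 2. TYMS, for thymidylate synthase, had a log2 change of 0.12 ± 0.11. The 56 G2/M genes had a median of -0.02 and 0 calls in either count (camera adjusted p = 0.937), with HMGB2 at -0.02 ± 0.18. CDKN1A, which encodes the cell cycle inhibitor p21, fell by 1.38 (SE 0.21), from 533 ± 208 (SD, n = 2) to 217 ± 61.8 (SD, n = 4), the only one of 15 CDK inhibitors and pocket proteins to pass (0 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.167), and GADD45A had 0.27 ± 0.24. Among 32 apoptosis regulators 0 passed (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.979), and CYCS, for cytochrome c, had 0.25 ± 0.11.

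**Figure D4:**
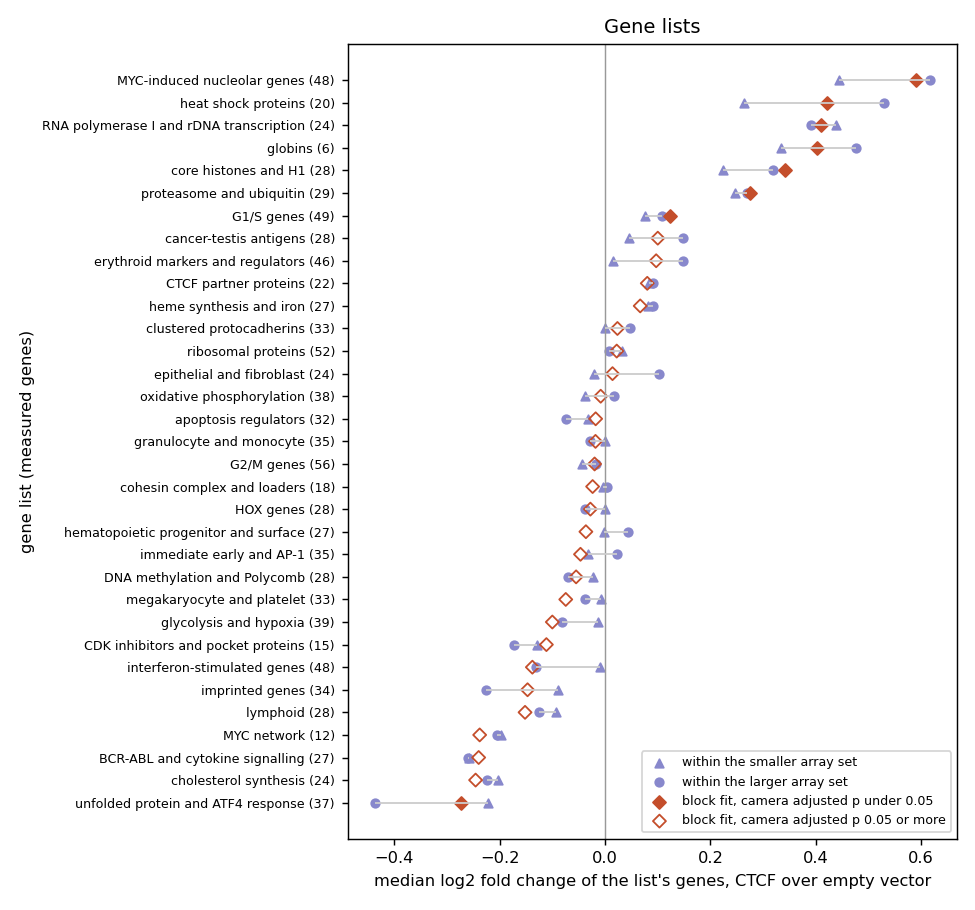
Median log2 fold changes, CTCF over empty vector, are drawn for the 33 gene lists with 5 or more measured genes, as diamonds for the blocked fit and as triangles and circles for the values within the smaller and larger array sets. Filled diamonds mark the 8 lists with a camera adjusted p under 0.05, 7 shifted upward and the unfolded protein and ATF4 response downward, before any estimate of the correlation between genes.

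Markers of other blood lineages and tissues changed one by one. TUBB1, a platelet tubulin, rose by 1.40 ± 0.23 as 1 of 33 megakaryocyte and platelet genes (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.864), while SRGN had 0.13 ± 0.12. FCGR2A, an Fc receptor, fell by 1.19 (SE 0.19) as 1 of 35 granulocyte and monocyte genes (0 and 3 over the list alone; 0.937), and CEBPB had -0.18 ± 0.30. CD3D, a T cell receptor chain, fell by 1.04 (SE 0.12) as 1 of 28 lymphoid genes (0 and 2; 0.288). That list had 0.0983 without the block and passed downward there with dim probe sets left out (0.0327), array weights (0.0318), the replicate block (0.0168), and without empty vector array 2 (0.0337) or CTCF array 4 (0.0407), but had an adjusted p = 0.548 with an estimated correlation. KIT, the stem cell factor receptor, fell by 2.15 (SE 0.20), from 148 ± 102 to 26.1 ± 13.4, as 1 of 27 progenitor and surface genes (1 and 4; 0.979), with ITGB1 at -0.52 ± 0.19. COL1A2 was the 1 of 24 epithelial and fibroblast genes to pass in both fits (0 and 1; 0.979), and COL1A1 and COL3A1, which fibroblasts express with it, had 0.07 ± 0.22 and 0.00 ± 0.12. Another of the 5 COL1A1 probe sets, chosen here after its values were seen, fell by 1.32 (SE 0.19), and the other 4 did not pass. COL3A1 read 6627 and 6114 in the smaller array set and 146 to 165 in the larger set, across both groups.

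TAF3, a TFIID subunit, rose by 0.82 ± 0.11 among 22 partner proteins of CTCF (1 higher and 0 lower, as over the list alone; camera adjusted p = 0.187). Of 18 cohesin genes 0 passed by either count (0.937), and RAD21, a core cohesin subunit, had values of 4119 ± 29.6 and 3526 ± 740. Among 34 imprinted genes, NAP1L5 rose by 1.27 ± 0.20 and DLK1 fell (1 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.106), and GNAS had -0.25 ± 0.14. Of 28 cancer-testis antigens, 4 rose and 1 fell (7 and 3 over the list alone), among them MAGEB1, PAGE5 by 1.70 ± 0.15 and, downward, PAGE1 by 1.44 (SE 0.21). That list had a camera adjusted p of 0.0534 with the block and 0.0364 without it, and 0.536 and 0.395 with an estimated correlation, and PRAME had -0.05 ± 0.12. Without the block camera gave the list 0.0583 after quantile normalization, 0.0626 with array weights and 0.146 with the replicate block. It gave 0.133 on ranks and 0.0517 without CTCF array 1. With the block, leaving out either array of the smaller set leaves the contrast to the larger set alone. With the block its adjusted p was 0.0336 without empty vector array 1, 0.0453 without CTCF array 2 and 0.0313 without CTCF array 4. The 28 genes of DNA methylation and Polycomb (4 and 3 over the list alone; 0.979), 28 HOX genes (0 and 0; 0.979) and 33 clustered protocadherins (0 and 1; 0.517) had 0 calls over all genes, and their brightest members DNMT1, HOXB2 and PCDHB13 had -0.02 ± 0.18, 0.34 ± 0.17 and -0.10 ± 0.13.

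The remaining lists concerned signalling and metabolism. UBE2L6, an interferon-induced ubiquitin-conjugating enzyme, fell by 1.55 (SE 0.16) as 1 of 48 interferon-stimulated genes (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.141), and IFITM1 had 0.17 ± 0.12. ID1, an inhibitor of helix-loop-helix factors, rose by 1.40 ± 0.18 as 1 of 27 genes of BCR-ABL and cytokine signalling, a list in which 3 were higher and 9 lower over the list alone (0.0963, and 0.0243 without CTCF array 1, but 0.806 with an estimated correlation; without the block 0.149, and 0.0467 and 0.0429 without empty vector array 1 and CTCF array 1), and SOCS2 had -0.28 ± 0.23. Of 35 immediate early and AP-1 genes, SPRED1 rose by 0.94 ± 0.11, and PHLDA1 and IER3 fell by 1.68 and 0.74 (2 and 3 over the list alone; 0.979). BNIP3, a mitochondrial protein induced by hypoxia, rose by 1.20 ± 0.14 as 1 of 39 glycolysis and hypoxia genes (8 and 8; 0.979), and ENO1 had 0.24 ± 0.11. Cholesterol synthesis (24 genes; 0.141) and oxidative phosphorylation (38 genes; 0.937) had 0 calls in either count, with SCD at -0.61 ± 0.15 and ATP5MC3 at 0.13 ± 0.11. Camera's direction was opposite in sign to the list median for the cohesin, epithelial and fibroblast, progenitor, HOX, glycolysis and oxidative phosphorylation lists.

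Of 482 runs of 40 consecutive measured genes along the chromosomes, 0 passed in camera in either fit, also with an estimated correlation. With runs of 20 genes 1 passed without the block, and with dim probe sets left out 1 passed with it.

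The authors' deposited table lists 768 probe sets, 311 higher and 457 lower, each with a fold change whose lower bound is at least 1.5 and a difference of means of at least 90. All 768 had the same direction here, in both fits and within both array sets, 756 had an unadjusted p under 0.05 without the block, and 463 passed the blocked fit, 180 higher and 283 lower, against 6 without the block. Another 554 probe sets that passed the blocked fit lie outside the authors' deposited table. The table was chosen on these same arrays, so its directions are not independent evidence. Among its probe sets with 1 gene name, the largest fold changes, as the authors' deposited table gives them, were 119 for MAP2K5, 48.6 for SLIT2 and 34.1 for PWAR6 upward, and -46.8 for SPX, -38.7 for PRSS3 and -37.6 for TFPI2 downward. These 6 also passed the blocked fit. MAP2K5, a MAP kinase kinase, rose by 2.74 ± 0.26 and SLIT2, an axon guidance ligand, rose by 3.42 ± 0.22, while SPX, for the peptide spexin, fell by 3.08 (SE 0.21). For MAP2K5 only 1 of 6 probe sets was higher, 1 fell, and both empty vector arrays are listed at 1.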

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

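The tests of a labelling batch, of RNA degradation and of the array sets behind the list shifts were chosen after the results were seen, as was the count of COL1A1 probe sets for fibroblast RNA, after 3 other measures, and for the exchange of labels the deciding measure was set after values were seen. In the 4 CTCF arrays, 15 of 93 values tested (16.1%, where chance gives about 5%) had 1 array far from the others, by the gap to the nearest array divided by the range of all 4. In 13 of the 15 the lone array was CTCF array 4, the only CTCF array of the smaller set. The 5% would hold for exchangeable arrays and independent values, which the array sets contradict, so the 2 shares are not a test. The sets were drawn on the spike-ins, so CTCF array 4 standing apart in bioB and bioC is no separate result. Below the others it had ADD2 (265 against 507 to 567; gap 0.852 of the range), FTL (0.842), HSPD1 (0.837), NAP1L5 (0.877), PRSS3 (14.2 against 58.2 to 69.6; 0.863), RPS16 (0.957), SEL1L (0.899), SPRED1 (0.928), TAF3 (0.887) and the bioB spike-in (0.871). Above them it had PCDHB13 (301 against 91.5 to 113; 0.833), the bioC spike-in (0.903) and the 3' minus 5' difference of ACTB (0.91 against 0.22 to 0.28; 0.904). CTCF array 2 was apart for CTCF (1614 against 1311 to 1332; 0.923), and CTCF array 1 for HDAC9 (332 against 150 to 167; 0.870).

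The split of the arrays into 2 sets that cross the groups was the largest structure in the data, and 22321 probe sets (40.9%) differed between the sets with the group in the fit. A labelling or hybridization batch is a candidate explanation, since clustering the human probe sets and clustering the spike-in probe sets placed 6 of 6 arrays alike, and spike-in RNA does not come from the cells. An exchange of labels between the 2 arrays of the smaller set is argued against: of the 500 probe sets with the lowest p in the larger set alone, where 0 passed the threshold, 97% had the same sign in the smaller set. RNA degradation cannot be told apart from the batch, because only 1 of the 3 transcripts with 5' and 3' control probe sets, ACTB, had a higher difference in both arrays of the smaller set, and 3 transcripts are too few to decide. No biological explanation of the split was tested.

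The shift of 8 gene lists between the groups was set against a trend with expression level and against the array sets. Among 10000 random lists matched on mean expression, the unfolded protein and ATF4 response lay at percentile 0.03 and the other 7 lists at 99.2 to 100, so 8 of 8 lay outside the central range, which argues against a trend with expression level. Of the 9 lists past the threshold without the block, 8 also passed in the same direction with it, and the block kept 73.0% to 94.8% of their medians, which argues against the sets as the whole cause. The ninth, the cancer-testis antigens, went from an adjusted p of 0.0364 to 0.0534 with a median of 0.10 in both (quartiles -0.28 and 0.38 without the block, -0.06 and 0.38 with it), so its call ended near the threshold with its median unmoved. What stays open is whether the shifts come from CTCF, from the single transfectant or from the empty vector cells used as baseline. The correlation between genes stays open too, since 0 lists passed with an estimated correlation (camera adjusted p = 0.536 with the block).

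The fall of COL1A2 could come from fibroblast RNA in the empty vector samples, in which case COL1A1, which fibroblasts express with it, would fall too. Of the 5 COL1A1 probe sets 1 fell with the block (30.7 and 91.1 in the empty vector arrays, 7.71 to 25.9 in the CTCF arrays; log2 change -1.32 ± 0.19), and the 4 others did not pass, with -0.31 to 0.24. Of 7 other fibroblast markers (COL5A1, DCN, FBN1, LUM, POSTN, TAGLN and THY1), 0 of 25 probe sets passed, and their brightest had -0.21 to 0.69. These brightest probe sets read 3.62 to 123 in the empty vector arrays, where COL1A2 read 1572 and 1808. Little of these markers was thus read there, but levels of different probe sets cannot be set against each other. From most of these values a fall could hardly show, so they do not decide. Among 22 further genes that fibroblasts express, COL6A3, S100A6, FN1, VIM and LGALS1 had a probe set that fell, and 0 genes had one that rose. In all 8 of their 70 probe sets fell, several of them for FN1 alone, a larger share than the 723 of 54613 over all probe sets. COL6A3 and S100A6 fell by 2.47 and 2.95. VIM and LGALS1 fell by only 0.89 and 0.73 and kept means of 4333 and 3087 in the CTCF arrays. Such an excess could come from fibroblast RNA, but the genes were picked after values were seen, so it does not decide. The shares are also not matched on expression, and probe sets of 1 gene are not independent. The COL1A1 probe sets disagree, and levels of different probe sets cannot be set against each other, so fibroblast RNA and a change in the transfected cells cannot be told apart here. The bound set beforehand, COL1A1 and COL3A1 both below 10% of COL1A2 in the empty vector arrays, was not met, with COL1A1 at 11.5% and 9.32% and COL3A1 at 421% and 8.06%, but it compares such levels and so decides nothing. COL3A1 read 6627 and 6114 in the smaller set of arrays, in both groups, and 146 to 165 in the larger.

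Whether chance groupings of arrays give as many calls cannot be settled by so few splits. Without the block, 2 of 15 splits of the arrays into 2 and 4 gave at least the 6 probe sets of the real split, and the highest other split, empty vector array 1 with CTCF array 4 against the rest, gave 19801, which is the split into array sets. With the block, 1 of 8 splits that take 1 array of each set, the real one, gave as many as 1017, and the highest other gave 0. Neither number of splits allows a share under 0.05.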

How the results depend on the processing

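The fits with the array set as a block and in the larger set alone were chosen after the data were examined, and the other alternatives before. The 6 calls without the block kept their sign under every alternative, and the 1017 with it did so too (961 of 961 tested with dim probe sets left out). Their selection on the same arrays largely fixes this. The number past the threshold moved widely, and the cause was not tested. Without the block, the number of probe sets past the threshold, the number of these at 2-fold or more and the number shared with the authors' deposited table were 18, 18 and 17 after quantile normalization, 73, 63 and 69 with a variance trend, 83, 57 and 80 with a pseudocount of 64, 1, 1 and 1 with a pseudocount of 1, 1017, 679 and 463 with the array set as a block, and 0, 0 and 0 in the larger set alone. A threshold of 0.01 left 1, and 1 at 2-fold or more. Leaving out each array gave 0 to 9 for all 3 counts, 9 without CTCF array 4 and 0 without each other array, 1.11 to 1.57 for CTCF, 7 to 10 lists and 0 to 0 runs of genes. CTCF was 1.29 and past the threshold with the block. An estimated correlation left 0 lists and fry 0, and runs of 20 genes gave 1 past the threshold. With the block, calls were 2642 with dim probe sets left out (fewer tested; 1 run of genes passed), 2567 with a variance trend (1077 at 2-fold or more), 1913 with array weights, 2140 with a pseudocount of 64 (426 at 2-fold or more) and 22 at 0.01 (22 at 2-fold or more). They were 2, 2 and 2 for the 3 counts with a pseudocount of 1 (CTCF 1.31, no longer past) and 0, 0 and 0 in the larger set alone (CTCF 1.14, no longer past). An estimated correlation left 0 lists, and fry, which tests no contrast with other genes, called 7. Of the 8 lists it kept globins, histones and proteasome, and lost MYC-induced nucleolar genes (0.0691), RNA polymerase I (0.108), G1/S (0.112), unfolded protein and ATF4 response (0.159) and heat shock (0.0542). It added the lymphoid, epithelial and fibroblast, imprinted and cancer-testis lists (0.037 each). Leaving out each array with the block gave 0 to 762 calls, 0 to 695 at 2-fold or more, 0 to 423 shared with the authors' deposited table, 1.14 to 1.51 for CTCF, 5 to 10 lists (5 without empty vector array 2) and 0 to 0 runs of genes. The 3' minus 5' difference of ACTB was higher in the smaller set than in the larger by 0.607 as deposited and by 0.741 after quantile normalization.

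The replicate number as a block gave 0, 0 and 0 for the 3 counts in limma, with 3085 probe sets at an unadjusted p under 0.05. Arrays with the same number deviated from their group means with r = -0.675 for replicate 1 and 0.696 for replicate 2, across probe sets. The 2 empty vector arrays deviate from their mean by equal and opposite amounts, and the array sets alone would give these signs. Whether the numbers pair the samples is therefore not shown.

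Signs turned in 8 of the named genes, none of them past the threshold in any of these settings. DNMT1 had 0.049 after quantile normalization, 0.044 after median centring (0.027 with the array set as a block) and 0.067 with the replicate block. HMGB2 had 0.012, 0.035 (0.023) and 0.051 in the same settings. GADD45A had -0.030 with array weights, CEBPB 0.027 with the replicate block, PRAME -0.049 with the array set as a block and -0.037 in the larger set alone, and PCDHB13 0.024 with the block after quantile normalization. Leaving out each array gave CEBPB -0.35 to 0.033 (-0.37 to 0.11 with the block), DNMT1 -0.13 to 0.043 (-0.11 to 0.036), HMGB2 -0.12 to 0.053 (-0.11 to 0.10), PCDHB13 -1.08 to 0.20, PRAME -0.11 to 0.14, RPS16 -0.0055 to 0.17 and SRGN -0.0067 to 0.16. The number of arrays and values near the floor limit what can be called.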

Other observations

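The test of neighbouring genes was chosen before its result was seen, and its repeats under other settings after. Genes that differed most between the array sets, with the group set aside, were in many cases far lower in one set than in the other. ANGPTL4 read 1920 and 3614 in the smaller set and at most 3.09 in the larger set, and FERD3L and NIPAL2 read 2316 and 1610, and 8080 and 8330, in the smaller set against at most 18.5 and 216 in the larger set. In the other direction, IHH read 299 and 352 in the smaller set and 2847 to 4333 in the larger set. These differences crossed both groups.

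Genes that passed in the blocked fit were neighbours more often than random placement gives, which was tested as a hypothesis that neighbouring genes change together. Of 507 placed genes past the threshold, 16 adjacent pairs went in the same direction, 13 down and 3 up, against a median of 8 in 10000 random placements (p = 0.0088, one-sided permutation) and of 9 in placements matched on expression (p = 0.0203). With pairs of the same symbol stem left out of the random placements the medians were 7 and 8 (p = 0.0017 and 0.0106, one-sided permutation). The pairs include P2RX1 with ATP2A3 (log2 changes with the block -3.13 and -2.31), DYNLT3 with SYTL5 (-1.79 and -3.21), GALNT12 with COL15A1 (-1.10 and -3.04), MGAT5 with TMEM163 (-0.94 and -2.69), MAPRE3 with TMEM214 (-1.07 and -0.81) and DNAJC30 with BUD23 (1.01 and 0.73). In 2 pairs the genes overlap, and leaving out pairs with the same symbol stem removed 0 pairs, so the filter did not remove HBD with HBBP1, both of the globin family. The repeats under other settings used the same arrays, so they add no separate evidence, and counted only pairs with different symbol stems. In them the excess appeared also after quantile normalization (19 pairs against a matched median of 9; p = 0.003, one-sided permutation), median centring (28 against 14; p = 0.0015), a pseudocount of 64 (59 against 41; p = 0.0025) and a variance trend (74 against 51; p = 0.0005, the smallest that 2000 permutations can give). The excess is consistent with domains of co-regulated genes, with small copy number differences between the transfectants, and with shared promoters, and the 16 pairs do not decide among these.

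The probe sets that passed without the block included 206042_x_at, annotated with 2 genes, whose values were 16.2 and 13.5 in the empty vector arrays and 586 to 643 in the CTCF arrays, with log2 changes of 4.36 and 4.43 within the smaller and larger array sets. The authors' deposited table gives it a fold change of 42.6.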
